A study of Homo sapiens with 15 samples.

How the data were processed

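RNA-seq was done on HEK293T cells treated for 4 h with DMSO, IXA1, IXA4, IXA6 or thapsigargin (Tg), with 15 samples in the series. Per the labels' protocols, 3 independent experiments were made and total RNA was extracted with a column kit before library construction at a sequencing company. The authors deposited a table of raw counts per gene symbol, which are whole numbers and sum to between 14160321 and 15726742 per library. Per the submitters' processing notes the genome build was GRCh37.p13; the aligner, the counting tool and whether counting used strand are not given in the sources used here. The authors also deposited tables of log2 fold changes with p-values and adjusted p-values for each compound, and per the submitters' processing notes DESeq was used; per the file headers the columns are those of its results table, and the reference group is not named in them. In the IXA tables the deposited test statistic has the opposite sign to the log2 fold change, and the log2 fold change was used. Those tables were only set beside the genes called and the log2 fold changes found here, also to weigh whether the same libraries were used.

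The count table holds 13243 genes and 15 count columns. Of these, 14 matched a sample title and 1 matched none and was not used in any step, so IXA1 has 2 libraries. The unmatched column bears the code IXA3, which no sample title has, and replicate number 3, and no column is named for IXA1 replicate 3. Whether it is that sample is not settled here, and every count of genes with IXA1 rests on leaving it out. The fewest counts that any gene has, summed over the 14 libraries, is 73, so genes with very low counts are not in the table. Of the 13243, 22 bear a date in place of a gene name (0.249% to 0.282% of counts). They stayed in the fit and are not named. No mitochondrially encoded gene of the 13 listed was measured. Gene symbols were used as the table gives them, with older symbols of list members looked up. No coordinates are given, because the annotation at hand is of another build; a GRCh38.p14 gene table served only to find which genes neighbour each other. Near-identical paralogs such as HSPA1A and HSPA1B, readthrough genes and overlapping genes can share reads, and their values are uncertain.

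Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, the default expression filter, which removed none of the 13243 genes, and the quasi-likelihood test in a single fit of all groups without other covariates, so that all groups share an estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each of 10 comparisons at 0.05. CPM are counts scaled by library size and TMM factors. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 18 lists with at least 2 measured genes, and again with an estimated correlation. The value given for a list is the mean log2 fold change of its members, and 95% intervals are from a linear model of the list's mean log2 CPM per library and cover the spread between libraries only. For every list that passed, mean, median and test had the same sign; among lists that did not pass they differed in some, as with heat shock genes in IXA1 and IXA4 and PERK/ISR targets in IXA6. The 19 lists were written before the data were examined, from general knowledge of the pathways. They cover XBP1s, ATF6 and PERK/ISR targets, heat shock, NRF2, metallothioneins, RIDD substrates, immediate early genes, NF-kB, ER translocation, ER folding, ER-associated degradation, N-glycosylation, ER-Golgi transport, cholesterol synthesis, p53, mitosis, mitochondrial genes and markers of other cell types.

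Named genes follow a rule fixed before the data were examined. Against DMSO it takes the 8 largest rises and 4 largest falls among genes past the threshold with a mean of at least 2 CPM over all libraries and every treated library beyond every DMSO library. It adds the 3 largest changes of each of 5 stress lists, up to 2 called members of each other list, and 8 panel genes. Between compounds it takes the 3 largest differences each way and 4 panel genes. With 1 column unused, the rule ran on 14 libraries. Rows without a gene name or with a provisional locus name were passed over. Members behind counts of 5 or fewer that fall outside this rule were named after their values were seen. Overlaps of calls were set beside those of independent lists and beside 20 simulations of unchanged groups that share simulated DMSO libraries.

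The test was tried on simulated counts with 200 changed genes and the 32 XBP1s targets raised 1.25-fold, the latter counted among calls only. For simulated IXA1 against DMSO, over 13201 genes, it recovered 38.8%, 82.1% and 95.5% of genes changed 1.25-, 1.5- and 2-fold, with 12 false calls among 174. For simulated IXA4 against DMSO, over 13199 genes, it recovered 44.8%, 83.6% and 97.0%, with 12 false calls among 190. Changes near 1.25-fold are therefore often missed at this depth and number of replicates. Replicate libraries were compared by chi-square per degree of freedom over genes, which ran from 2.50 to 9.53, so no pair agreed within sampling noise. Alternatives tried were other size factors (RLE), no filter, a filter of at least 100 counts in 3 libraries, DESeq2 1.42.0, a fit of the compared groups alone, replicate number as a block, a minimum fold of 1.2, each library left out, an estimated correlation, and list members in no other list.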

Results

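Gene expression was measured by RNA-seq in HEK293T cells, an established line of human embryonic kidney cells, after 4 h with vehicle (DMSO) or a compound. The compounds were IXA1, IXA4 and IXA6, described in the series as activators of the IRE1/XBP1s branch of the unfolded protein response (UPR), and thapsigargin (Tg). Tg blocks the calcium pump of the endoplasmic reticulum (ER) and activates all branches of the UPR. Counts of 14 libraries were analysed, with 3 for DMSO, IXA4, IXA6 and Tg and 2 for IXA1. Total counts ranged from 14160321 to 15726742 per library over 13243 genes, and the biological coefficient of variation between replicates was 5.66%. Doses are not given in the sources used here, so compounds were compared at matched times but at unknown doses. The labels speak of independent experiments, and the edgeR p-values of single genes measure the spread between these cultures. The camera p-values of lists set a list's genes against the other genes and depend on the correlation assumed between genes. Their size is therefore not a measure of replication over cultures. Fisher's exact test and the permutation tests are over genes and do not measure that spread either.

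The comparison of IXA1 with DMSO asked which genes changed with this compound. Among the stress-related genes, CHAC1, an enzyme that degrades glutathione, rose 4.12-fold (log2 fold change 2.04 ± 0.14 SE, adjusted p = 1.87e-09), from 2.97 ± 0.52 CPM (counts scaled by library size; SD, n = 3) to 12.2 ± 0.51 CPM (SD, n = 2). DNAJB9, an ER co-chaperone, rose 2.23-fold (log2 fold change 1.16 ± 0.08 SE, adjusted p = 3.49e-09). HERPUD1, a component of ER-associated degradation, rose 2.14-fold (log2 fold change 1.10 ± 0.06 SE, adjusted p = 4.80e-11). The neutral amino acid transporter gene SLC1A4 rose 2.06-fold (log2 fold change 1.04 ± 0.10 SE, adjusted p = 1.98e-07). XBP1 itself, the transcription factor downstream of IRE1, rose 2.05-fold (log2 fold change 1.03 ± 0.05 SE, adjusted p = 9.14e-12), whereas the IRE1 gene ERN1 was at 1.10-fold (log2 fold change 0.14 ± 0.11 SE, adjusted p = 0.588). Gene-level counts do not separate spliced from unspliced XBP1 mRNA. The other largest rises were in ADM2, which encodes a peptide hormone (2.82-fold, from only 0.693 ± 0.39 to 1.96 ± 0.50 CPM), PRR19 (2.19-fold) and FICD, an ER enzyme that modifies BiP (1.83-fold). The largest falls were in DGAT2, an enzyme of triacylglycerol synthesis (log2 fold change -1.33 ± 0.19 SE, adjusted p = 0.000176), and TXNIP, a thioredoxin-binding protein (log2 fold change -1.32 ± 0.11 SE, adjusted p = 3.28e-08), followed by TMOD1 (-1.04) and TPGS1 (-0.94). The value of TMOD1 is uncertain, since it neighbours TSTD2 and the sum of the 2 was 43.1 ± 2.7 CPM with DMSO and 44.6 ± 0.0018 with IXA1 (SD).

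By gene list, XBP1s targets rose with IXA1 by a mean of 0.29 on the log2 scale (camera, adjusted p = 1.40e-24). Of 32 members 15 rose and none fell when adjusted over all genes, and 25 rose when adjusted over the list alone, which includes the COPII coat gene SEC24D (0.76 ± 0.07 SE) and SLC33A1 (0.66 ± 0.06 SE). ATF6 targets rose by a mean of 0.36 (adjusted p = 1.95e-20), with 12 of 16 members higher by either adjustment, among them HSPA5, which encodes the chaperone BiP (0.65 ± 0.05), and SYVN1, an ubiquitin ligase of ER-associated degradation (0.56 ± 0.08). PERK/ISR targets, genes of the PERK branch and integrated stress response, rose by a mean of 0.41 (adjusted p = 4.26e-21). Of the 29 measured members 13 rose and 18 rose when adjusted over the list alone, with SESN2 at 0.86 ± 0.09. DDIT3, which encodes CHOP, was at 0.28 ± 0.13 (adjusted p = 0.308), and NUPR1, at about 1 CPM or less in the compared groups, was at 1.19 ± 0.46 (adjusted p = 0.196). The heat shock list had a mean of -0.0046 (adjusted p = 0.999), with 1 of 19 members higher, HSPB1 (0.30 ± 0.07), while HSPA8 was at -0.23 ± 0.07 (adjusted p = 0.0608), HSPB8 at -0.37 ± 0.44 (adjusted p = 0.745) and HSPA1A at 0.10 ± 0.09 (adjusted p = 0.635). Adjusted over the list alone, 1 heat shock gene rose and 1 fell. No member of the oxidative stress (NRF2) list passed over all genes (list mean 0.0010, adjusted p = 0.985), and 2 of 17 rose when adjusted over the list alone, with MAFG at 0.29 ± 0.09, NQO1 at -0.26 ± 0.17 and HMOX1, which encodes haem oxygenase, at -0.26 ± 0.09.

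With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 306 of 13243 genes changed with IXA1, 241 higher and 65 lower, of which 9 rose and 4 fell at least 2-fold. Leaving out any library of the comparison left 82 to 181 genes (70 to 147 higher and 10 to 36 lower), a fit of the 5 libraries alone gave 648 and a minimum fold of 1.2 gave 22. The calls of ADM2, ALG2, FICD, HSPB1, IDI1, JUND, PER1, PRR19, TMOD1 and TPGS1 were each lost without at least 1 of the libraries. The rise of ATF6 targets no longer passed camera when only members in no other list were kept (mean 0.18, adjusted p = 0.0586). Of the 16 ATF6 targets, 9 are also in the ER folding list and 4 in the ER-associated degradation list. That setting therefore drops much of the list and says little about the rest of it.

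**Figure D1:**
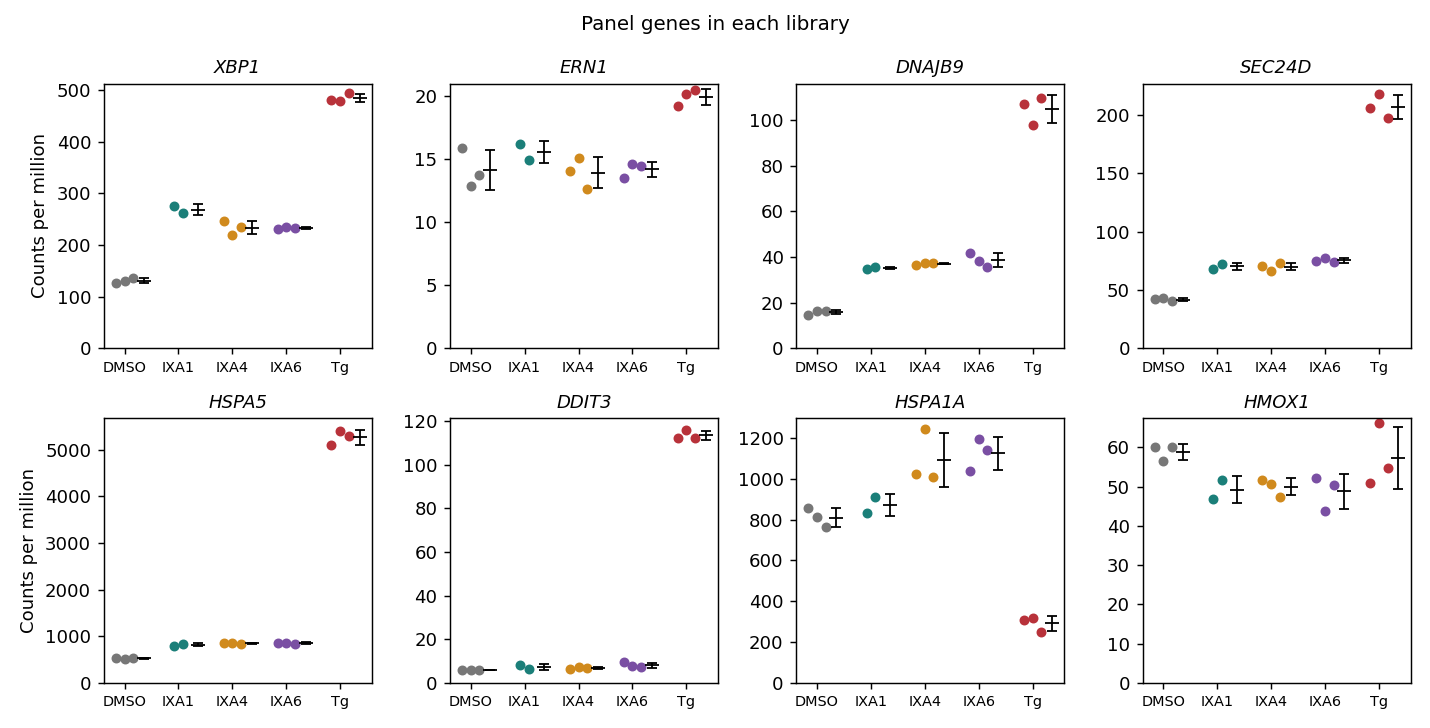
CPM of 8 panel genes in each library (y axis, from 0) by treatment (x axis); points are libraries, and the black bars beside them are the mean ± SD (n = 3, or n = 2 for IXA1). XBP1, DNAJB9, SEC24D and HSPA5 lie above DMSO with every compound and highest with Tg, while HSPA1A falls to 292 ± 36 CPM with Tg.

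The comparison of IXA4 with DMSO asked the same of this compound. DNAJB9 rose 2.36-fold (log2 fold change 1.24 ± 0.08 SE, adjusted p = 1.83e-10), from 15.7 ± 0.89 to 37.1 ± 0.37 CPM (SD, n = 3 each). FICD rose 2.07-fold (log2 fold change 1.05 ± 0.17 SE, adjusted p = 0.000726), HERPUD1 1.84-fold (log2 fold change 0.88 ± 0.06 SE, adjusted p = 4.08e-10) and XBP1 1.78-fold (log2 fold change 0.84 ± 0.05 SE, adjusted p = 6.69e-11). CHAC1 rose 1.82-fold (log2 fold change 0.87 ± 0.15 SE, adjusted p = 0.00193). Rises of similar size were found in CREB3L2, an ER-anchored transcription factor (1.77-fold), SLC1A4 (1.74-fold) and SEC24D (1.69-fold), while ERN1 was at 0.984-fold (adjusted p = 0.969). DGAT2 fell the most (log2 fold change -1.21 ± 0.16 SE, adjusted p = 8.51e-05), followed by the smooth muscle myosin gene MYH11 (-1.04), TXNIP (-0.69) and the cell adhesion gene BCAM (-0.65).

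XBP1s targets rose with IXA4 by a mean of 0.32 (camera, adjusted p = 1.98e-41), with 16 of 32 members higher over all genes and 28 adjusted over the list alone; SLC33A1 rose by 0.72 ± 0.06 SE. ATF6 targets rose by a mean of 0.37 (adjusted p = 1.27e-33), with 12 of 16 higher and 15 adjusted over the list alone, including HSPA5 (0.69 ± 0.05) and the disulfide isomerase gene PDIA4 (0.58 ± 0.05). PERK/ISR targets rose by a mean of 0.12 (adjusted p = 4.75e-06), with 2 of 29 members higher, CHAC1 and the cystine transporter gene SLC7A11 (0.40 ± 0.07), and 7 adjusted over the list alone. DDIT3 was at 0.20 ± 0.12 (adjusted p = 0.658) and NUPR1 at -0.28 ± 0.51 (adjusted p = 0.914). In the heat shock list 2 of 19 members rose by either adjustment, the near-identical paralogs HSPA1A (0.43 ± 0.08) and HSPA1B (0.50 ± 0.08), whose reads cannot be assigned with certainty. HSPB8 was at -0.44 ± 0.39 (adjusted p = 0.783), and the list mean was 0.01 with a test direction of down (adjusted p = 0.970). No NRF2 list member passed over all genes and 1 of 17 fell when adjusted over the list alone (list adjusted p = 0.253), with HMOX1 at -0.24 ± 0.08, SRXN1 at -0.22 ± 0.06 and PIR at 0.13 ± 0.09.

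In all, 106 genes changed with IXA4, 95 higher and 11 lower (edgeR), of which 2 rose and 2 fell at least 2-fold. Leaving out any library of the comparison left 69 to 95 genes (61 to 84 higher and 4 to 11 lower), with the lowest count without DMSO replicate 2. A fit of the 6 libraries alone gave 198 and a minimum fold of 1.2 gave 21. The calls of DERL3, GFPT1, HSPA1A, INSIG1, JUN, MYH11 and SLC7A11 were each lost without at least 1 of the libraries.

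IXA6 raised the same kinds of ER genes without a rise of the PERK/ISR list past the test. DNAJB9 rose 2.45-fold (log2 fold change 1.29 ± 0.08 SE, adjusted p = 6.93e-11), from 15.7 ± 0.89 to 38.6 ± 3.2 CPM (SD, n = 3 each). SEC24D rose 1.81-fold (log2 fold change 0.86 ± 0.06 SE, adjusted p = 1.14e-09), and CREB3L2 and XBP1 each rose 1.78-fold (log2 fold changes 0.83 ± 0.05 and 0.83 ± 0.05 SE). PLPP5, a lipid phosphatase gene, rose 1.73-fold (log2 fold change 0.79 ± 0.11 SE, adjusted p = 0.000173), and FICD, HERPUD1 and SLC33A1 rose 1.78-, 1.72- and 1.68-fold. ERN1 was at 1.00-fold (adjusted p = 0.996). The largest falls were in DGAT2 (log2 fold change -1.33 ± 0.17 SE, adjusted p = 2.45e-05), BCAM (-0.72), C2orf81 (-0.57) and RTN4RL2 (-0.51).

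XBP1s targets rose with IXA6 by a mean of 0.36 (camera, adjusted p = 2.63e-34), with 22 of 32 members higher and 28 adjusted over the list alone. ATF6 targets rose by a mean of 0.37 (adjusted p = 1.98e-24), with 13 of 16 higher and 15 adjusted over the list alone, including HSPA5 (0.71 ± 0.05 SE) and PDIA4 (0.58 ± 0.05 SE). The PERK/ISR list had a mean of -0.0020, a positive median and a test direction of up (adjusted p = 0.763). Of its 29 members 2 rose, DDIT3 (0.46 ± 0.12) and the folate enzyme gene ALDH1L2 (0.28 ± 0.06), and 1 fell, the amino acid transporter gene SLC7A5 (-0.24). Adjusted over the list alone, 2 rose and 2 fell, and NUPR1 was at -0.51 ± 0.53 (adjusted p = 0.669). Heat shock genes rose by a mean of 0.08 (adjusted p = 0.0239), but the adjusted p was 0.152 with an estimated correlation. In that list 4 of 19 members rose, with 4 higher and 1 lower adjusted over the list alone; the paralogs HSPA1B (0.58 ± 0.08) and HSPA1A (0.47 ± 0.08), which can share reads, were among them with CHORDC1 (0.25) and HSPE1 (0.20), and HSPB8 was at -0.35 ± 0.39 (adjusted p = 0.690). No NRF2 list member changed by either adjustment (list adjusted p = 0.447), with HMOX1 at -0.27 ± 0.08, SRXN1 at -0.17 ± 0.06 and GSR at -0.14 ± 0.07.

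With IXA6, 303 genes changed, 200 higher and 103 lower (edgeR), of which 5 rose and 3 fell at least 2-fold. Leaving out any library other than IXA6 replicate 3 left 118 to 164 genes, 102 to 123 of them higher and only 15 to 41 lower, and a minimum fold of 1.2 gave 25, with 2 lower. The calls of C2orf81, DDIT3, FICD, IER2, JUN, PGM3 and RTN4RL2 were each lost without at least 1 of the libraries, and the heat shock call was lost without DMSO replicate 1 (adjusted p = 0.0743).

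Tg gave a far broader change. CHAC1 rose 23.3-fold (log2 fold change 4.54 ± 0.11 SE, adjusted p = 6.25e-20) to 69.1 ± 2.9 CPM (SD, n = 3), and DDIT3 rose 19.3-fold (log2 fold change 4.27 ± 0.09 SE, adjusted p = 3.00e-21). HSPA5 rose 10.1-fold (log2 fold change 3.33 ± 0.05 SE, adjusted p = 7.38e-24), from 524 ± 18 to 5270.1 ± 159.6 CPM. HERPUD1 rose 15.8-fold, ADM2 16.8-fold, LBH 20.2-fold and OSTN, which encodes a secreted peptide, 12.1-fold. XBP1 rose 3.70-fold and ERN1 1.41-fold (log2 fold change 0.49 ± 0.09 SE, adjusted p = 0.000178). The largest falls were in DGAT2 (log2 fold change -3.60 ± 0.22 SE, adjusted p = 4.19e-12), RUSC1-AS1 (-2.78), BCAM (-2.58) and the collagen gene COL26A1 (-2.49). FAXDC2 rose 11.3-fold (log2 fold change 3.50 ± 1.06 SE, adjusted p = 0.0125), but its counts and those of RUSC1-AS1 differed over 8-fold between the libraries of the IXA6 group, and its call was lost without Tg replicate 1 (adjusted p = 0.0581), so both values are uncertain.

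All 32 XBP1s targets rose with Tg (mean 1.06, camera adjusted p = 2.07e-31), as did all 16 ATF6 targets (mean 2.08, adjusted p = 3.25e-28) and all 29 PERK/ISR targets (mean 1.81, adjusted p = 1.64e-34), over all genes and adjusted over the list alone. Examples are DNAJB9 (2.74 ± 0.07 SE), SEC24D (2.32 ± 0.06) and DNAJC3 (1.97 ± 0.05) of the XBP1s list, SDF2L1 (2.49 ± 0.07) of the ATF6 list and NUPR1 (3.21 ± 0.34) of the PERK/ISR list. Heat shock genes fell by 0.32 on the log2 scale on average (adjusted p = 3.02e-05), with 12 of 19 lower and 2 higher by either adjustment. HSPA8, the constitutive HSP70 gene, was at -1.54 ± 0.06 and HSPA1A at -1.47 ± 0.08, whereas HSPB8 rose by 1.56 ± 0.31 and DEDD2 by 0.29 ± 0.07. In the NRF2 list 2 of 17 rose and 2 fell, 2 and 1 adjusted over the list alone (list adjusted p = 0.657), with GCLC (0.70 ± 0.06) and MAFG (0.46 ± 0.08) higher, SRXN1 (-0.44 ± 0.06) and TKT (-0.17 ± 0.06) lower and HMOX1 at -0.04 ± 0.08 (adjusted p = 0.756). In all, 4746 genes changed with Tg, 2493 higher and 2253 lower (edgeR), of which 206 rose and 80 fell at least 2-fold; a minimum fold of 1.2 gave 1396.

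**Figure D2:**
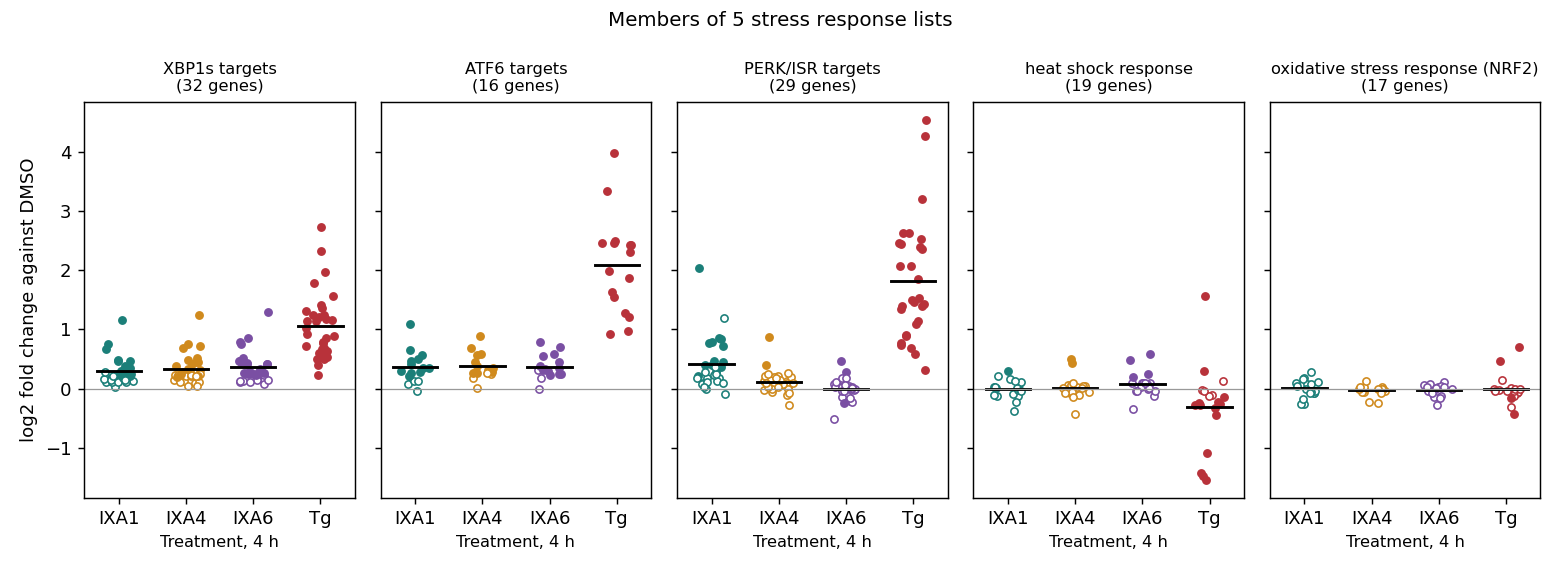
Log2 fold change against DMSO (y axis) of each member of 5 stress lists by treatment (x axis); filled points passed the edgeR test at adjusted p under 0.05, open points did not, and black bars are list means. The PERK/ISR means run from 0.41 with IXA1 to 0.12 with IXA4, -0.0020 with IXA6 and 1.81 with Tg.

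Lists of ER functions rose with each of the 4 treatments. ER folding and disulfide genes rose by a mean of 0.26, 0.31, 0.30 and 1.23 with IXA1, IXA4, IXA6 and Tg, with 14, 16, 16 and 23 of 27 members higher (16, 21, 20 and 23 adjusted over the list alone). ER translocation genes rose by a mean of 0.20, 0.18, 0.21 and 0.52, with 7, 6, 11 and 19 of 24 higher (16, 14, 15 and 20 adjusted over the list alone), including SSR1 (0.48, 0.48, 0.52 and 1.14). In that list SEC61A1 rose by 0.46 with IXA1 and 0.44 with IXA4, and SSR3 by 0.47 with IXA6 and 1.17 with Tg. ER-Golgi transport genes rose by a mean of 0.15, 0.13, 0.13 and 0.43, with 7, 6, 7 and 20 of 29 higher (11, 9, 12 and 20 adjusted over the list alone), including KDELR1 with IXA1 (0.42) and BET1 with IXA4, IXA6 and Tg (0.42, 0.48 and 1.05). ER-associated degradation genes rose by a mean of 0.15, 0.14, 0.12 and 0.88, with 4, 5, 7 and 15 of 21 higher (5, 7, 9 and 16 adjusted over the list alone), including DERL3 with IXA4 (0.45) and Tg (2.46) and VIMP with IXA6 (0.39). N-glycosylation genes rose by a mean of 0.09, 0.10, 0.09 and 0.42, with 3, 4, 5 and 17 of 26 higher (6, 8, 7 and 19 adjusted over the list alone), including ALG2 with the 3 IXA compounds (0.46, 0.55 and 0.57), STT3A with IXA1 (0.34), PGM3 with IXA6 (0.58), and GFPT1 (0.32 with IXA4 and 1.57 with Tg) and GMPPB with Tg (1.41). The value of PGM3 is uncertain, since adding its neighbour DOPEY1 removed 49.1% of its spread in CPM within groups. Together PGM3 and DOPEY1 were at 127.6 ± 4.4 CPM with DMSO and 162.7 ± 8.6 with IXA6 (SD). The calls of the XBP1s and ATF6 lists with all 4 treatments and of the PERK/ISR list with IXA1, IXA4 and Tg held with an estimated correlation, the highest adjusted p being 0.0317 for PERK/ISR targets with IXA4. The 20 calls of the 5 ER function lists also held with an estimated correlation, at adjusted p up to 0.0297. The ER lists share 26 memberships with the XBP1s list and 13 with the ATF6 list; among members in no other list, ER-associated degradation no longer passed with any IXA compound, and N-glycosylation no longer passed with IXA6 (adjusted p = 0.221). Without DMSO replicate 1, N-glycosylation with IXA6 had an adjusted p of 0.0566. With Tg, 3 ER-associated degradation genes (MAN1B1, NPLOC4 and UBE2G2) and 3 ER-Golgi genes (ERGIC1, ERGIC3 and SEC24B) fell. Adjusted over the list alone, 1 N-glycosylation gene fell with IXA1 and 2 with Tg, 2 ER-associated degradation genes with IXA6 and 3 with Tg, and 1 ER-Golgi gene with IXA6 and 3 with Tg.

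Cholesterol synthesis genes rose with IXA1, IXA4 and IXA6 by means of 0.14, 0.11 and 0.14 (adjusted p = 5.10e-06, 7.53e-06 and 1.23e-06), with 5, 2 and 5 of 19 members higher (8, 4 and 8 adjusted over the list alone). IDI1, an enzyme of isoprenoid synthesis, rose with each (0.37, 0.35 and 0.39), INSIG1, a regulator of sterol synthesis, rose by 0.35, 0.24 and 0.31 in the same order, and the sterol carrier gene STARD4 rose by 0.40 with IXA6. With Tg the list mean was 0.25 (adjusted p = 0.00560; 0.0843 as the adjusted p with an estimated correlation), with 10 higher and 2 lower by either adjustment; STARD4 was higher (2.84-fold). Mitosis genes fell by 0.28 on average with Tg (adjusted p = 3.68e-06), with 13 of 16 lower (14 adjusted over the list alone), among them MKI67 (-0.63) and AURKA (-0.51). The same list had a mean of -0.08 with IXA4 (adjusted p = 0.000472; no member changed over all genes, 1 fell adjusted over the list alone), -0.06 with IXA1 (adjusted p = 0.0557, and 0.0315 without DMSO replicate 1) and -0.02 with IXA6 (adjusted p = 0.540).

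Immediate early genes rose with Tg by a mean of 0.45 (adjusted p = 0.00316; the adjusted p was 0.0567 with an estimated correlation), with 9 of 17 higher and 2 lower (EGR1 and IER5) by either adjustment, led by FOS (2.58) and FOSB (1.80). Among the same genes JUND rose with IXA1 (0.34), JUN rose with IXA4 (0.22) and IXA6 (0.23), and IER2 fell with IXA6 (-0.35), with no call of the list. Reported substrates of IRE1-dependent decay (RIDD) fell by 0.31 on average with Tg (adjusted p = 0.0318; the adjusted p was 0.0847 with an estimated correlation and 0.0613 without Tg replicate 1), with 6 of 9 lower, including CD59 (-1.25) and TGOLN2 (-0.88), and 1 higher, PER1 (0.70). That list did not pass with IXA1 (mean 0.08, adjusted p = 0.361, PER1 higher at 0.39), IXA4 (mean -0.08, adjusted p = 0.0712, but 0.0257 without DMSO replicate 3 and 0.0468 without IXA4 replicate 2) or IXA6 (mean -0.06, adjusted p = 0.147). The NF-kB list (adjusted p = 0.960, 0.417, 0.679 and 0.515 with IXA1, IXA4, IXA6 and Tg), the p53 list (0.855, 0.338, 0.399 and 0.309) and the metallothionein list (0.999, 0.878, 0.447 and 0.515) passed with no treatment. No member changed with an IXA compound over all genes, and 1 metallothionein gene rose with IXA6 adjusted over the list alone. By either adjustment, 3 of 10 NF-kB genes, 4 of 14 p53 genes and 1 of 4 metallothionein genes rose with Tg and 1 p53 gene fell, BTG2 (-0.52). In these lists, with Tg, RELB (1.38), NFKB2 (0.48), TNFRSF10B (0.61), CDKN1A (0.60) and MT1X (0.70) rose. Of 15 markers of other cell types 4 were measured and none changed in any of these 4 comparisons (list adjusted p = 0.960, 0.338, 0.540 and 0.515).

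**Figure D3:**
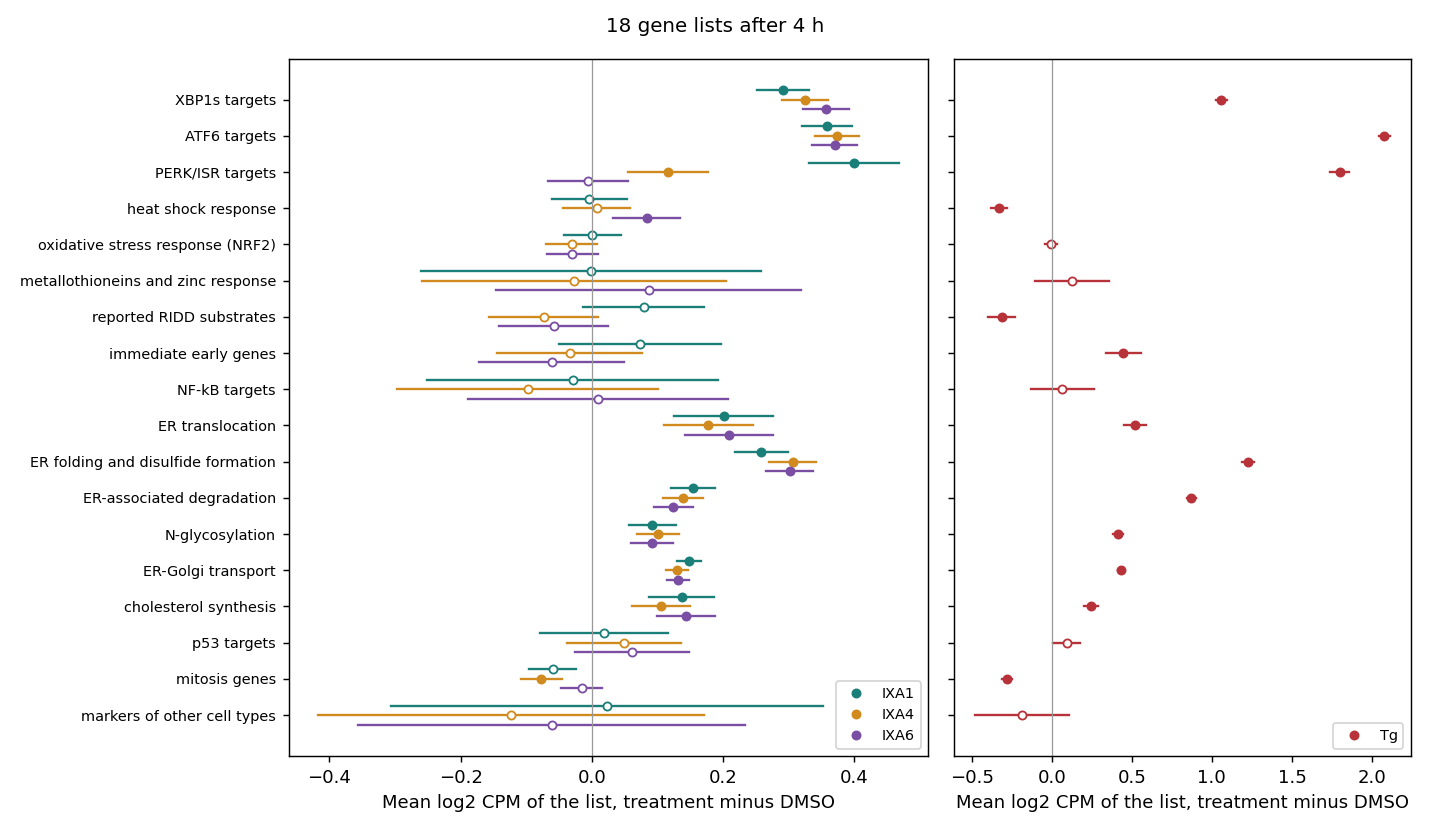
Mean log2 CPM of each of 18 gene lists in treated minus DMSO libraries (x axis, log2 scale; the Tg panel has its own range), with 95% intervals over the libraries as lines. Filled points passed camera at adjusted p under 0.05. The ER function lists lie above 0 with every treatment, and the PERK/ISR list lies at -0.01 with IXA6.

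Genes called in common were counted for each pair of treatments. IXA4 and IXA6 shared 82 higher and 3 lower genes, against 1.43 and 0.086 expected of independent lists and 0 and 0 in simulated unchanged groups that share simulated DMSO libraries. IXA1 and IXA4 shared 62 higher and 3 lower genes (1.73 and 0.054 expected), and IXA1 and IXA6 shared 69 and 3 (3.64 and 0.506 expected). With Tg, IXA1 shared 141 higher and 38 lower genes and 22 changed in opposite directions, IXA4 shared 91 and 5 with 6 opposite, and IXA6 shared 175 and 57 with 7 opposite. The expected counts with Tg were 45.4 and 11.1, 17.9 and 1.87, and 37.7 and 17.5. The shared lower genes were DGAT2, TXNIP and ARRDC4 for IXA1 and IXA4, DGAT2, PIGQ and UBL4A for IXA1 and IXA6, and DGAT2, BCAM and SREBF1 for IXA4 and IXA6. Those of IXA4 and Tg were DGAT2, BCAM, EFNB3, NOTCH3 and RDH11. Simulated unchanged groups gave means of at most 0.1 higher and 0.15 lower genes per pair. Since no gene was changed in them, few calls could arise at all. They therefore cannot show how much shared DMSO libraries add to overlaps among changed genes. The DMSO libraries are too few to split, and part of the excess of shared genes may come from sharing them. The covariance of log2 fold changes across 11950 genes, which are not independent replicates, was 0.0138 for IXA4 and IXA6 against 0.00708 simulated, 0.00921 against 0.00705 for IXA1 and IXA4, and 0.00760 against 0.00717 for IXA1 and IXA6. For IXA1, IXA4 and IXA6 with Tg it was 0.0208, 0.0202 and 0.0263 against 0.00704, 0.00717 and 0.00719 simulated. The correlations were lower than simulated in 5 of the 6 pairs: 0.396 against 0.436 simulated for IXA1 and IXA4, 0.286 against 0.441 for IXA1 and IXA6, and 0.338 against 0.432, 0.395 against 0.495 and 0.451 against 0.495 for IXA1, IXA4 and IXA6 with Tg. Only IXA4 and IXA6 lay above, at 0.627 against 0.491. With no gene changed, the simulated correlations come from the shared DMSO libraries alone. Changes particular to 1 treatment add spread and lower a correlation, so a value under the simulated one does not show that treatments are less alike. The covariances lay above the simulated ones in all 6 pairs.

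The IXA compounds were then compared directly. IXA1 gave higher CHAC1 than IXA4 (2.26-fold; log2 fold change 1.18 ± 0.13 SE, adjusted p = 1.57e-05) and IXA6 (4.14-fold; log2 fold change 2.05 ± 0.14 SE, adjusted p = 6.85e-09). The PERK/ISR list was higher with IXA1 than with IXA4 by a mean of 0.29 (camera adjusted p = 8.03e-13, and 0.0235 as the adjusted p with an estimated correlation; 9 of 29 members higher, 16 adjusted over the list alone) and than with IXA6 by 0.41 (adjusted p = 1.63e-15, and 0.0122 as the adjusted p with an estimated correlation; 16 higher, 20 adjusted over the list alone). DDIT3 did not pass in either comparison (0.08 ± 0.13 and -0.18 ± 0.13 SE; adjusted p = 0.814 and 0.409). Against IXA4, NOVA2 (0.88) and TSTD2 (0.71) were also higher and TMOD1 (-1.10), GALNTL6 (adjusted p = 0.00902) and PALM2 (-0.85) lower. TSTD2 and TMOD1 are neighbours and moved in opposite directions, with a sum of 44.6 ± 0.0018 CPM with IXA1 and 41.6 ± 1.5 with IXA4 (SD), so both values are uncertain. Against IXA6, ADM2 (2.84-fold) and the readthrough gene TBC1D7-LOC100130357 (1.67, with reads that TBC1D7 can share) were higher, and TXNIP (log2 fold change -1.08 ± 0.11 SE, adjusted p = 2.87e-06), MAT2A, a methionine adenosyltransferase (log2 fold change -0.87 ± 0.07 SE, adjusted p = 1.45e-07), and C12orf60 (-0.84) lower.

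The other branch lists did not pass between IXA compounds. The XBP1s list differed by -0.03 for IXA1 minus IXA4 (95% interval -0.07 to 0.01, camera adjusted p = 0.473), -0.07 for IXA1 minus IXA6 (-0.11 to -0.03, adjusted p = 0.0645) and -0.03 for IXA4 minus IXA6 (-0.07 to 0.0028, adjusted p = 0.106). The ATF6 list differed by -0.02 (-0.05 to 0.02), -0.01 (-0.05 to 0.03) and 0.0031 (-0.03 to 0.04) in the same order. For DNAJB9 the log2 differences were -0.08 ± 0.08, -0.13 ± 0.08 and -0.06 ± 0.07 SE, for SEC24D 0.0030 ± 0.06, -0.10 ± 0.06 and -0.10 ± 0.06, and for HSPA5 -0.05 ± 0.05, -0.06 ± 0.05 and -0.02 ± 0.05, none past the test. IXA4 and IXA6 differed in the PERK/ISR list by 0.12 (interval 0.06 to 0.18, adjusted p = 0.000106), but the adjusted p was 0.184 with an estimated correlation; no member passed over all genes and 7 were higher adjusted over the list alone. Heat shock genes were lower with IXA4 than with IXA6 by 0.07 on average (adjusted p = 0.00931) and mitosis genes by 0.06 (adjusted p = 0.0237), both at an adjusted p of 0.184 with an estimated correlation. DDIT3 was at -0.26 ± 0.11 for IXA4 minus IXA6 (adjusted p = 0.488).

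In counts of genes, 342 differed between IXA1 and IXA4 (252 higher with IXA1), 974 between IXA1 and IXA6 (600 higher with IXA1) and 0 between IXA4 and IXA6 by edgeR, where 1222 genes had an unadjusted p under 0.05 and DESeq2 called 21. Leaving out a library gave 11 to 166 genes for IXA1 against IXA4 (2 to 34 of them lower) and 113 to 1128 for IXA1 against IXA6 (28 to 463 lower), with the lowest count in both without IXA1 replicate 1. A minimum fold of 1.2 left 4, 9 and 0 genes, and the calls of ADM2, C12orf60, GALNTL6, NOVA2, PALM2, TBC1D7-LOC100130357, TMOD1 and TSTD2 were each lost without at least 1 library.

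Each IXA compound was also set against Tg, for which 4485 (IXA1), 4556 (IXA4) and 4108 (IXA6) genes differed by edgeR. The lowest genes relative to Tg were DDIT3, LBH and OSTN with IXA1 (-3.99, -3.95 and -3.61), DDIT3, LBH and CHAC1 with IXA4 (-4.07, -4.04 and -3.67), and CHAC1, ADM2 and LBH with IXA6 (-4.55, -4.08 and -4.02). DGAT2 was higher than with Tg by 2.27, 2.39 and 2.27. Other genes among the 3 largest higher values were RUSC1-AS1 (uncertain, as above) and BCAM with IXA1 (2.99 and 2.20), COL26A1 and HSPA1L with IXA4 (2.01 and 1.93), and HSPA1B and HSPA1A with IXA6 (2.00 and 1.94). The XBP1s list was lower than with Tg by means of -0.77, -0.74 and -0.70 (camera adjusted p = 3.07e-24, 3.05e-25 and 2.37e-25), with 31, 30 and 30 of 32 members lower (31, 30 and 31 adjusted over the list alone). The ATF6 list was lower by -1.72, -1.70 and -1.71 and the PERK/ISR list by -1.40, -1.70 and -1.82, with all 16 and all 29 members lower in each. HSPA5 differed from Tg by -2.68 ± 0.06, -2.64 ± 0.05 and -2.62 ± 0.05 SE, SEC24D by -1.56, -1.56 and -1.46, and DNAJB9 by -1.58, -1.50 and -1.44. DDIT3 with IXA6 was at -3.81. A minimum fold of 1.2 left 1199, 1123 and 1031 genes, and without IXA1 replicate 1 the count for IXA1 was 2949.

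The authors' deposited table lists 553 genes for IXA1, 204 for IXA4, 475 for IXA6 and 3693 for Tg at an adjusted p under 0.05, leaving out rows named by a number. Of these 242, 96, 263 and 3683 were also called by edgeR, each in the same direction. That table gives no adjusted p for 3846, 3590, 4105 and 518 of its rows, in the same order, and these could not be shared. They include DGAT2 and FICD with each IXA compound and CHAC1 with IXA1 and IXA4. In the authors' deposited table DNAJB9 stands at log2 fold changes of 1.16, 1.24, 1.29 and 2.74 and HSPA5 at 0.65, 0.69, 0.71 and 3.33, in the order IXA1, IXA4, IXA6 and Tg. Over all genes, log2 fold changes in the authors' deposited table differed from those of edgeR by medians of 0.0291, 0.00121, 0.000198 and 0.00193 in the same order. With IXA1, XBP1 is at 1.06 and SYVN1 at 0.46 in the authors' deposited table and at 1.03 and 0.56 by edgeR. Which libraries entered the authors' fit is not given in the sources used here, and IXA1 has 2 libraries here. The median difference of 0.0291 for IXA1, against at most 0.00193 for the others, argues against a fit on the same 2 IXA1 libraries. The counts for IXA1 therefore need not rest on the same samples.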

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

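All the tests of explanations in this part were chosen after the results were seen. The difference of a list between compounds was tested directly, and 4 differences of stress lists passed among the 3 comparisons of IXA compounds. PERK/ISR targets were higher with IXA1 than with IXA4 (mean log2 difference 0.29) and IXA6 (0.41), and higher with IXA4 than with IXA6 (0.12; adjusted p = 0.184 with an estimated correlation). Heat shock genes were lower with IXA4 than with IXA6 (-0.0693, adjusted p = 0.00931; 0.184 as the adjusted p with an estimated correlation).

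The higher PERK/ISR list with IXA1 than with IXA6 was weighed against 3 explanations. A single unusual IXA1 library is argued against, since the mean difference was 0.36 or more with either IXA1 library left out and the list still passed. A stronger ER stress response over all branches is argued against too, for the lists as a whole. The upper interval bounds of the XBP1s and ATF6 list differences reached only 0.0259, while the lower bound for the PERK/ISR list was 0.34. These bounds are of list means, and single members lay on either side. Variation of this list between cultures of the same group is argued against by its range within a group. That range was at most 0.10, from the 2 IXA1 libraries, against a difference of 0.41 between the compounds. A shift common to all cultures of a group would not show in that range, so it stays open. Doses are not given in the sources used here and IXA1 has 2 libraries, so whether dose or compound sets IXA1 apart stays open and was not tested.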

How the results depend on the processing

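The alternative without genes whose counts jump within a group was chosen after seeing the data. All others were fixed before the data were examined. No result that passed reversed direction in the alternatives tried on it. Outside the comparisons with DMSO, only the XBP1s, ATF6 and PERK/ISR lists were put through the alternatives for lists. The heat shock and mitosis calls for IXA4 against IXA6 were tried with an estimated correlation only. Results that did not pass could change sign, as the PERK/ISR list with IXA6 did by library means without IXA6 replicate 1. A minimum fold of 1.2 reduced the counts to 22 (IXA1), 21 (IXA4), 25 (IXA6) and 1396 (Tg) against DMSO, 4 and 9 for IXA1 against IXA4 and IXA6, and 1199, 1123 and 1031 for IXA1, IXA4 and IXA6 against Tg, as its construction asks for larger changes. Fitting only the compared groups gave 648 for IXA1 and 198 for IXA4 against DMSO, 1156 for IXA1 against IXA4 and 13 for IXA4 against IXA6; the cause was not tested. DESeq2 gave 594 for IXA1 against IXA4 and 21 for IXA4 against IXA6, the latter also 3 with at least 100 counts in 3 libraries and 9 without the genes whose counts jump; the cause was not tested. Among named genes, DESeq2 lost the calls of TMOD1 with IXA1 and IER2 and PGM3 with IXA6 and added HSPA8 with IXA1 and HMOX1 with IXA6. Of 201 named-gene results, 171 had the same outcome by DESeq2. Those to which DESeq2 gave no adjusted p could not be checked. Fitting only the compared groups lost RTN4RL2, DDIT3 and IER2 with IXA6 and added HSPA8 with IXA1 and HMOX1 with each IXA compound. A minimum fold of 1.2 lost 49 calls of named genes, 1 of them with Tg (NFKB2). With only members in no other list, ATF6 targets with IXA1 had a mean of 0.18 (adjusted p = 0.0586), over fewer genes. With an estimated correlation, which does not enter the mean, heat shock genes with IXA6 (mean 0.0823) had an adjusted p of 0.152. Leaving out each library gave 82 to 181 genes for IXA1, 69 to 95 for IXA4 and 118 to 319 for IXA6 against DMSO, 11 to 166 for IXA1 against IXA4, 113 to 1128 for IXA1 against IXA6, 0 to 2 for IXA4 against IXA6 and 2949 to 4778 for IXA1 against Tg, with fewer libraries in each fit; heat shock genes with IXA6 had means of 0.0723 to 0.091, without a call when DMSO replicate 1 was out (adjusted p = 0.0743). Where 1 IXA1 library was left, it was assumed to vary like the other groups. No pairing of libraries by replicate number was seen. Correlations of same-number deviations ran from -0.148 to 0.112 over 26 pairs, with 1 above 0.1, and 6 of 14 libraries correlated best with their own number. With so few libraries per group this cannot exclude that a number marks the same experiment across groups, which the labels do not state. With the replicate number as a block, counts were 247 (IXA1), 96 (IXA4), 265 (IXA6) and 4621 (Tg) against DMSO, 339, 927 and 0 between IXA compounds, and 4268, 4453 and 3971 against Tg, and no list call changed; the calls of PRR19, TMOD1 and TPGS1 with IXA1 and RTN4RL2 with IXA6 were lost. RLE size factors changed no count by over 1.5 times and no list call, and among named genes only the call of RTN4RL2 with IXA6 was lost, and the case of no filter moved nothing because every gene passed the filter. With DESeq2 the overlaps of higher genes stayed within 1.5 times in all 6 pairs, while those of lower genes went from 3 to 5 for IXA1 and IXA6, from 3 to 2 for IXA4 and IXA6 and from 5 to 9 for IXA4 and Tg; the cause was not tested. At this depth, genes near 1 CPM, such as NUPR1 with standard errors of 0.46 to 0.53 with the IXA compounds, allow only large changes to be seen.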

Other observations

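The tests of explanations and hypotheses in this part were chosen after the results were seen, except the splits of libraries. With all 3 IXA compounds 57 genes were higher, 56 of them also with Tg, and 1 gene was lower, DGAT2. The exception with Tg was INSIG1 (0.09, adjusted p = 0.191). The 57 included 12 of 32 XBP1s targets, 11 of 16 ATF6 targets and 13 of 27 ER folding genes (Fisher's exact test over the 13243 genes, adjusted p = 1.49e-20, 1.30e-22 and 1.38e-23), and none of the 29 PERK/ISR targets. Of the 57, 23 were in no list. Among these, chosen after their values were seen, EIF2AK3, which encodes PERK, rose by 0.65, 0.53 and 0.64 with IXA1, IXA4 and IXA6 and by 1.82 with Tg. UGDH, an enzyme of UDP-glucuronate synthesis, rose by 0.34, 0.54, 0.65 and 1.47.

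MAT2A, a methionine adenosyltransferase, and TXNIP, a thioredoxin-binding protein, are given for all treatments, a choice made after their values were seen. MAT2A was lower with IXA1 than with DMSO (-0.68 ± 0.07 SE) and lower with Tg (-0.83 ± 0.07), and was at 0.01 ± 0.06 with IXA4 and 0.19 ± 0.06 with IXA6. TXNIP was lower with IXA1 (-1.32) and IXA4 (-0.69), at -0.24 with IXA6 (adjusted p = 0.147) and higher with Tg (0.42). The direct difference of IXA1 from IXA4 was -0.69 ± 0.07 for MAT2A and -0.63 ± 0.11 for TXNIP, both past the test.

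Counts of 20 genes jumped within a group, with at least 100 counts in the highest library and over 8 times the lowest plus 1. CHMP3 ran from 79 to 1413 counts, while its readthrough gene RNF103-CHMP3 ran from 378 to 1782 and their sum from 1541 to 1884. For 10 of the 20, adding the counts of a neighbouring gene removed at least 50% of the within-group spread. When the neighbours were exchanged at random among the 20 genes, 0.499 did so on average and at most 6 in 100000 exchanges (1-sided permutation test, p = 1.00e-05). The 10 make 9 pairs, as NBL1 and MINOS1-NBL1 are each other's neighbour. For these 10, reads assigned to either of the neighbouring genes fit as an explanation by this test. The other 10, such as SLCO5A1 with 214 to 7807 counts, stay open, and no biological explanation was tested. Of the named genes, a neighbour removed at least 50% of the spread in CPM for TMOD1 (55.2%, by TSTD2), TSTD2 (57.4%, by TMOD1) and RUSC1-AS1 (52.6%, by FDPS). Without the 20 genes, 9 genes differed between IXA4 and IXA6 in place of 0.

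A hypothesis is that the IXA compounds act more on XBP1s targets than on ATF6 targets, relative to what Tg does to each gene. The median change as a part of the Tg change was 27.6%, 28.9% and 34.9% for 32 XBP1s targets with IXA1, IXA4 and IXA6, and 18.2%, 17.4% and 17.7% for 16 ATF6 targets. The differences were 9.42, 11.5 and 17.2 percentage points (2-sided permutation test over genes, 100000 resamples, adjusted p = 0.0560, 0.0118 and 0.00606). The values for 29 PERK/ISR targets were 17.7%, 5.71% and 0.568%. Genes are not independent replicates, and XBP1s targets also rose less with Tg, so an effect of the size of the response remains open and was not tested.

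With 3 libraries against 3, the 10 splits are too few for a share under 0.05. Every other split also mixes both groups, so a real difference between them widens its spread and lowers its count of genes. The other counts therefore do not show what chance alone would give. In fits of 6 libraries the real and highest other counts of changed genes were 198 and 5 (IXA4 against DMSO), 436 and 7 (IXA6 against DMSO), 4162 and 4 (Tg against DMSO), 13 and 7 (IXA4 against IXA6), 4108 and 2 (IXA4 against Tg) and 3275 and 3 (IXA6 against Tg), with 1 of 10 splits as large in each. For lists called they were 12 and 6, 7 and 7, 13 and 11, 3 and 1, 11 and 12, and 11 and 9 in the same order, with 1, 2, 1, 1, 2 and 1 of the splits as large. For IXA6 against DMSO and IXA4 against Tg, another split thus called as many lists or more. Counts of lists do not set the real groups apart there. With IXA6 against DMSO the fit of 6 libraries also called fewer lists than the fit of all groups, and the cause was not tested.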
